A study of Mus musculus with 6 samples.

How the data were processed

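Small RNA libraries of 6 pools of retinas were analysed, 3 from control mice (floxed Dicer1 without the iCre75 transgene) and 3 from cKO mice (with it), at 4 weeks of age. Per the labels' protocols, each library was made from 1 µg of total RNA of 6 retinas with an adapter-ligation small RNA kit, amplified by 11 rounds of PCR, selected on a gel for miRNA-sized inserts and sequenced in a shared 50-base single-end run, so that sequencing run and genotype are not confounded. Replicate numbers and genotype were taken from the labels' descriptions. The labels call the samples biological replicates, and which mice went into which pool is not given in the sources used here.

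The authors deposited RPKM values, in which reads are divided by the precursor's length and by the library's total, for 855 miRNA precursors. Per the submitters' processing notes, Bowtie and the mm9 build were used, and the Bowtie version, the annotation, the treatment of reads that fit several places and any filter are not given in the sources used here. The reference at hand is of another build (GRCm38), so no coordinates are printed, and it served only for precursor lengths and sequences, matched by name for 811 precursors. Each deposited RPKM value times the precursor's length was a whole multiple of a step that is fixed per library. This gave whole reads for 100.0% of 4866 values (tolerance 0.01 reads), and with them each library's total. Lengths of 40 further precursors were inferred as the shortest that gave whole reads, a rule that returned the annotated length in 100.0% of 397 precursors where it was tested. Totals ranged from 5480940 to 7478237 reads, at which 1 read in a precursor of 75 bases is worth 1.78 to 2.43 RPKM. Reads summed over precursors came to 1.55 to 1.86 times the library total, so reads that fit several precursors appear at each of them and shares of precursors can add to more than the total. Values of near-identical copies such as mir-138-1 and mir-138-2, or mir-204 and mir-211, are therefore not separate measurements.

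Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(RPKM + 1), cKO minus control, for 461 precursors with a mean of at least 10 RPKM over the 6 libraries, without further scaling. Tests were two-sided, and adjusted p values follow Benjamini and Hochberg with a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low precursors. The 17 fixed lists were tested against all other tested precursors with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The retinal pigment epithelium list (mir-204, mir-211) and the Dicer-independent list (mir-451a) had 2 and 1 tested precursors, below the minimum of 3, and only their members' values are given. Shares and the median shift were tested by exact permutation of the 6 libraries, which cannot give p below 0.1. Intervals are Wilson 95% intervals from scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

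The design, the lists, the alternatives and the rule for naming precursors were fixed before the data were examined. The rule takes the 15 largest rises and 15 largest falls among precursors past the threshold with a mean of at least 100 RPKM and no overlap between groups (only 4 falls qualified), the 10 most abundant precursors, all members of the miR-183 cluster, pigment epithelium and Dicer-independent lists, mir-124, mir-9 and mir-21, and up to 4 abundant members of each other list. Of near-identical copies usually only a single copy is named. Alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, sums of near-identical precursors, a replicate block and leaving out each library. Precursors were taken as near-identical when they shared a 20-base window with at most 1 mismatch. Added after seeing the data were totals without mir-182 reads and limma voom on the recovered whole reads, alone and with median-of-ratios scaling.

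The fit was tested on simulated data for this comparison, with 200 of 461 precursors changed. It recovered 76.1% of those changed 1.5-fold, 91.0% of those changed 2-fold and 98.5% of those changed 4-fold, and 1.12% of its calls were unchanged precursors. The simulation drew precursors independently with a common dispersion, left mir-182 unchanged and kept the library totals fixed. It therefore does not measure false calls that arise when the shared total shifts between genotypes.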

Results

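Small RNAs were sequenced from whole retinas of 4-week-old mice in which Dicer1 was deleted in rod photoreceptors by an iCre75 transgene (cKO), and from littermates that carried the same floxed Dicer1 alleles without the transgene (control). Dicer1 encodes the RNase that cuts most miRNA precursors to their mature form. There were 3 libraries per genotype, described as biological replicates, and each library came from a pool of 6 retinas. The values cover 855 miRNA precursors, of which 203 were listed at 0 in every library. Library totals worked out from the values were 7478237, 6894116 and 7061298 reads for control 1 to 3, and 6925715, 6914307 and 5480940 reads for cKO 1 to 3. Below, library reads means these totals, which appear to hold only reads at miRNA precursors and not all sequenced reads. Dicer1 mRNA, the deleted target itself, was not analysed here, so no value of the target checks the genotype labels.

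The first comparison concerned the makeup of the retinal miRNA pool with and without Dicer1 in rods. In control retina mir-182, a member of the miR-183 cluster that is abundant in photoreceptors and other sensory cells, took 54.7% ± 2.34 (SD, n = 3) of library reads. In cKO retina it took 30.2% ± 3.22 (SD, n = 3). The share of mir-181a-2, a miRNA of the inner retina, was 20.9% ± 0.829 in control and 34.2% ± 1.38 in cKO retina (SD, n = 3 each), so that mir-181a-2 exceeded mir-182 in cKO 2 and cKO 3. The share of mir-204 was 2.94% ± 0.217 against 5.72% ± 0.628 (SD, n = 3 each). In each of these shares the 3 cKO libraries lay on one side of the 3 control libraries, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow.

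Counting error was small beside the spread between libraries. For mir-182 the share in control 1 was 57.41% with a Wilson 95% interval of 57.37% to 57.44%, and in cKO 3 it was 27.74% with an interval of 27.71% to 27.78%. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. All 3 precursors of the miR-183 cluster together held 57.5% ± 1.42 of control and 32.6% ± 3.54 of cKO reads (SD, n = 3 each). As a share of summed RPKM the cluster made up 39.5% ± 1.10 in control and 19.4% ± 2.64 in cKO retina (SD, n = 3 each; exact two-sided permutation p = 0.1). The 10 most abundant precursors held 76.2% ± 1.12 and 70.7% ± 1.29 of summed RPKM (SD, n = 3 each; exact two-sided permutation p = 0.1). Their difference was -5.54 percentage points, and -1.70 points once near-identical precursors were summed.

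**Figure D1:**
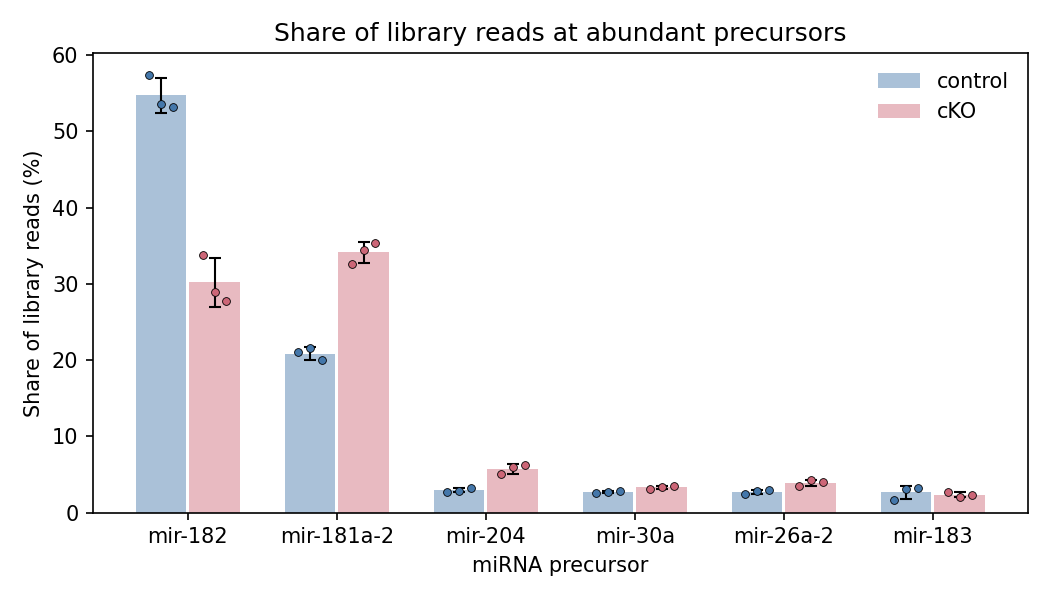
Share of library reads (totals worked out from the values, which appear to hold only reads at miRNA precursors), in percent, at 6 abundant miRNA precursors. Bars are means, error bars SD and points single libraries (n = 3 per genotype); mir-182 lies between 53.2% and 57.4% in control and between 27.7% and 33.8% in cKO libraries.

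Of 461 precursors with a mean RPKM of at least 10, 320 rose and 8 fell in cKO retina as the values were deposited, and 133 did not pass (limma, Benjamini-Hochberg adjusted p below 0.05). The median precursor was 1.67-fold higher in cKO retina, a log2 fold change of 0.74, and 429 of 461 precursors (93.1%) were higher (exact two-sided permutation p = 0.1, the smallest possible). The library medians had a pooled SD of 0.10 on the log2 scale. In 339 precursors (73.5%) the cKO libraries did not overlap the control libraries, where chance gives 10%. The number that fell was 12 without control 1, 4 without control 2 and without control 3, and 5 without cKO 2 and without cKO 3. RPKM is relative to the total of its own library, so these values do not show whether a miRNA was higher or lower per retina.

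The split of calls turned with the scaling. Median-of-ratios scaling, which sets the typical precursor equal between libraries, left 10 that rose and 46 that fell, with a median log2 fold change of 0.014. Quantile normalization gave 12 and 29 (median 0.042), totals without the 10 most abundant precursors 57 and 29 (median 0.23). Totals without the reads at mir-182, an alternative chosen after seeing the data, gave 20 and 36 (median 0.12). Under all 5 scalings the precursors mir-126, mir-127, mir-138-1, mir-138-2, mir-193a, mir-490 and mir-541 rose, and mir-96, mir-335, mir-483, mir-872, mir-1948, mir-1968 and mir-3086 fell. The reverse held for 7 precursors, among them mir-30a and mir-30d, which rose as deposited and fell with median-of-ratios scaling.

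The deepest fall among abundant miRNAs was that of mir-182, at 7295950 ± 311516 RPKM in control and 4024510 ± 429841 RPKM in cKO retina (SD, n = 3 each), a log2 fold change of -0.86 (SE 0.093; limma adjusted p = 2.4e-04). With median-of-ratios scaling it was -1.60 (adjusted p = 6.7e-05), and under quantile normalization the call ended at -0.63 (adjusted p = 0.14). Quantile normalization keeps only the rank of each value, which limits how far the most abundant precursor can differ. The call lost there therefore does not gauge the fall of mir-182. Its cluster neighbour mir-96 fell by 0.49 on the log2 scale (adjusted p = 0.048), although the groups overlapped. The third member, mir-183, did not pass at -0.11 (adjusted p = 0.68). Control 1 held 230841 RPKM of mir-183 against 432932 and 466232 in control 2 and 3, and without control 1 mir-183 fell by 0.43 (adjusted p = 0.023). Without control 2 or control 3 its log2 fold change was 0.024 or 0.077, and with median-of-ratios scaling it fell by 0.85 (adjusted p = 0.039).

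Among less abundant precursors, mir-483, which lies in the imprinted Igf2 gene, fell by 0.86 on the log2 scale (SE 0.19; adjusted p = 0.0027). The precursors mir-872 and mir-335 fell by 0.41 (SE 0.13; adjusted p = 0.021) and 0.35 (SE 0.14; adjusted p = 0.047). The other 3 falling precursors had means below 100 RPKM and were named after their values were seen: mir-1968 at -2.13 (SE 0.28), mir-3086 at -1.22 (SE 0.35) and mir-1948 at -1.53 (SE 0.54). The value of mir-1948, which had a mean of 13.5 reads per library, was -0.83 without cKO 1. The call of mir-872 ended without control 2, control 3, cKO 2 or cKO 3 (adjusted p = 0.055 to 0.077), that of mir-96 without the same libraries (adjusted p = 0.10 to 0.18), that of mir-335 without any library but control 1 (adjusted p = 0.057 to 0.16), and that of mir-1948 without any control (adjusted p = 0.061 to 0.080).

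Among precursors of at least 100 RPKM that passed and whose groups did not overlap, the highest rises were those of mir-138-2 and mir-138-1, near-identical copies of a miRNA of neurons, and of mir-541. The precursor mir-138-2 stood at 5447 ± 861 RPKM in control and 15801 ± 1386 RPKM in cKO retina (SD, n = 3 each), a 2.92-fold rise (log2 1.54, SE 0.15; limma adjusted p = 1.7e-04). The imprinted mir-541 rose 2.89-fold and its cluster partner mir-127 rose 2.49-fold, from 159255 to 390810 RPKM. The endothelial mir-126 rose 2.58-fold (log2 1.37, SE 0.17; adjusted p = 3.1e-04). Rises of 2.40- to 2.60-fold were also measured for mir-193a, mir-455, mir-879, mir-490, mir-377, mir-667, mir-1249, mir-497, mir-323 and mir-6236. With median-of-ratios scaling mir-138-2 stood at 0.81, mir-541 at 0.79, mir-126 at 0.63 and mir-127 at 0.58 on the log2 scale, while mir-455, mir-879, mir-377, mir-1249, mir-323 and mir-6236 no longer passed.

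**Figure D2:**
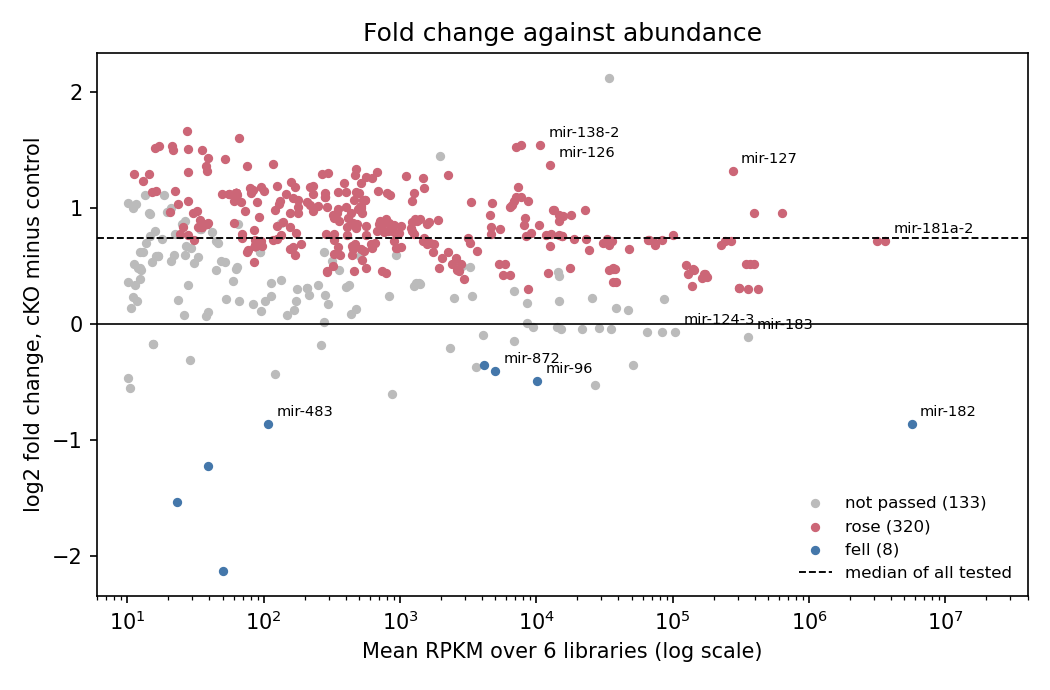
Log2 fold change, cKO minus control, against mean RPKM over 6 libraries on a log scale for the 461 tested precursors, coloured by call. The dashed line is the median of 0.74, and mir-182, the most abundant precursor, lies at -0.86; with median-of-ratios scaling the median is 0.014.

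Most of the abundant miRNAs of the retina rose as deposited and lost their call or turned sign with median-of-ratios scaling. As deposited mir-181a-2 of the inner retina rose 1.64-fold (log2 0.71, SE 0.080; adjusted p = 2.4e-04) and mir-9-2, a miRNA of neural progenitors and Müller glia, rose 1.65-fold, but with median-of-ratios scaling they stood at -0.023 and -0.015. The paired precursors mir-204 and mir-211, known from the retinal pigment epithelium, rose 1.94- and 1.95-fold, and at 0.22 and 0.23 no longer passed after that scaling. Smaller rises were those of mir-26a-2 at 0.52, mir-30d at 0.31 and mir-30a at 0.30, which with median-of-ratios scaling stood at -0.21, -0.43 and -0.44. The pan-neuronal mir-124-3 did not pass as deposited, at -0.071 (adjusted p = 0.68), and fell by 0.81 with median-of-ratios scaling (adjusted p = 0.0046). The glial and injury-linked mir-21a likewise stood at -0.14 as deposited and -0.88 after that scaling (adjusted p = 0.0021). The calls of mir-30a and mir-30d ended without control 2, cKO 2 or cKO 3 (adjusted p = 0.062 to 0.081 and 0.060 to 0.079). The precursor of mir-451a, which matures without Dicer in red cells, rose 2.14-fold as deposited (adjusted p = 0.0010) and stood at 0.36 (adjusted p = 0.20) with median-of-ratios scaling.

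Fixed lists of miRNAs were compared with all other tested precursors. In the imprinted Dlk1-Dio3 cluster 44 of 46 precursors rose and none fell (adjusted over the list alone, 44 rose), with a median log2 fold change of 1.06 (camera, preset correlation, adjusted p = 2.4e-06; adjusted p = 0.28 with an estimated correlation). Its abundant members mir-127, mir-434, mir-136 and mir-411 rose 2.49-, 1.98-, 1.80- and 2.14-fold, and the less abundant mir-541 rose 2.89-fold. After median-of-ratios scaling 3 members of the list rose. In the sensory miR-183 cluster 2 of 3 precursors fell (adjusted over the list alone, 1; camera adjusted p = 1.1e-07, and adjusted p = 0.16 with an estimated correlation). The light-regulated list adds mir-204 and mir-211 to that cluster: 2 rose and 2 fell, the same counts as adjusted over the list alone (camera, down, adjusted p = 0.0074; adjusted p = 0.20 with an estimated correlation). Of the proliferation-linked miR-17-92 family clusters 4 of 14 rose, including mir-25 (1.59-fold), and 2 adjusted over the list alone. This list stood below the other precursors (camera adjusted p = 0.0085; adjusted p = 0.20 with an estimated correlation) while its median was 0.35, and its most abundant member mir-92a-1 did not pass at -0.35. With median-of-ratios scaling mir-25 stood at -0.066 and mir-92a-1 fell by 1.08 (adjusted p = 0.0021). The 14 miR-17-92 precursors fall into 8 groups of near-identical copies, the 5 light-regulated into 4 and the 46 of Dlk1-Dio3 into 41. Counts of these lists are therefore not all of separate measurements. Without a filter on low values the calls of the light-regulated and miR-17-92 lists ended (adjusted p = 0.095 and 0.21), as did that of miR-17-92 with near-identical precursors summed (adjusted p = 0.36) and that of the light-regulated list with median-of-ratios scaling (adjusted p = 0.14). No list held its call with an estimated correlation, although 3 lists (miR-183 cluster, light-regulated and miR-17-92) had an unadjusted p below 0.05 there.

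In the other lists most named members rose as deposited, and no camera call was made. In the brain-wide neuronal list 15 of 18 rose, with mir-138-2 at the top and mir-129-1 at 1.92-fold, while the 3 copies of mir-124 did not pass (camera adjusted p = 0.49). In the inner retina and Müller glia list 19 of 23 rose (camera adjusted p = 0.15, and 0.0065 without cKO 1). With an estimated correlation its camera adjusted p was 0.61 to 0.96 over all settings. Camera gave up for this list, although its mean lay below the other precursors (difference -0.12). In the let-7 family 12 of 12 rose (camera adjusted p = 0.49), among them let-7f-2 at 1.32-fold. With median-of-ratios scaling let-7f-2 stood at -0.33 and the let-7 list was called down (camera adjusted p = 0.0032), with no member past the threshold. That call was lost with an estimated correlation (adjusted p = 0.70), and the 12 precursors fall into 2 groups of near-identical copies. Vascular miRNAs rose in 6 of 6 precursors (adjusted p = 0.79), with mir-143 of mural cells at 1.56-fold and mir-145a at 1.71-fold. Blood and microglial miRNAs rose in 4 of 8 (adjusted p = 0.93), with mir-486 of red cells at 1.66-fold and mir-150 of lymphocytes at 2.07-fold. In the gliosis and inflammation list 2 of 6 rose (adjusted p = 0.15), and mir-27a did not pass at 0.14 as deposited and fell by 0.60 with median-of-ratios scaling (adjusted p = 0.0072). The counts were 4 of 7 for skeletal and cardiac muscle (mir-133a-1 1.57-fold; adjusted p = 0.49), 6 of 8 for mirtrons (mir-668 1.85-fold; adjusted p = 0.49), 8 of 8 for the miR-15/16 family (mir-497 2.42-fold, mir-16-1 1.39-fold; adjusted p = 0.36) and 45 of 68 for the Sfmbt2 cluster (mir-467c 1.79-fold; adjusted p = 0.49). The mirtron list shares mir-668 with the Dlk1-Dio3 list, in which 44 of 46 precursors rose. The 68 Sfmbt2 precursors fall into only 2 groups linked by near-identical copies and the 23 of the inner retina into 10. The 18 neuronal precursors fall into 11 groups, the 6 vascular into 4, the 7 muscle into 4, and the 8 miR-15/16 and 8 epithelial into 6 each. The counts of these lists are therefore not of separate measurements. Over all tested precursors 320 of 461 rose as deposited. Of the epithelial, lens and cornea list 1 of 8 rose (adjusted p = 0.15); mir-184 and mir-31 stood at 2.12 (SE 0.88) and 1.45 (SE 0.72) and did not pass. Adjusted over the list alone these counts were equal, except for 3 muscle precursors. With median-of-ratios scaling the medians of these lists lay between -0.36 and 0.12, and 2 members or fewer of a list rose and 5 or fewer fell.

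The sign of the mean difference from the other precursors and the direction of camera differed for the vascular, epithelial, inner retina, let-7 and Sfmbt2 lists. Camera compares moderated t statistics, which depend on the standard error, and not fold changes. Medians were positive but camera gave down for the epithelial, gliosis, haematopoietic, miR-17-92, Sfmbt2 and muscle lists. The fry test, which asks whether members move one way and not whether they differ from other precursors, gave up for each list but the miR-183 cluster, and passed for each but the light-regulated (adjusted p = 0.15) and muscle lists (adjusted p = 0.075). These fry results are for values as deposited, where 429 of 461 precursors were higher in cKO retina. A fry result of up therefore does not set a list apart from the broad rise.

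Leaving out a library ended or made some calls of named list members, and those that ended kept their sign. The call of mir-143 ended without control 1, control 2, cKO 2 or cKO 3 (adjusted p = 0.084 to 0.15), and those of mir-133a-1 and let-7f-2 without control 2, cKO 2 or cKO 3 (adjusted p = 0.077 to 0.11 and 0.052 to 0.074). The call of mir-16-1 ended without control 1, control 2 or cKO 1 (adjusted p = 0.059 to 0.080). Over the 6 fits that each left out a library, log2 fold changes ran from 0.38 to 0.88 for mir-143, from 0.42 to 0.84 for mir-133a-1, from 0.33 to 0.49 for let-7f-2 and from 0.35 to 0.64 for mir-16-1. Without control 1 mir-92a-1 fell by 0.56 (adjusted p = 0.0041), and over the 6 fits its log2 fold change ran from -0.56 to -0.19. Without control 3 mir-184 and mir-31 rose, by 3.31 and 2.12 on the log2 scale (adjusted p = 0.0016 and 0.023), while without control 2 they did not pass, at 1.03 and 0.41 (adjusted p = 0.19 and 0.31). Without cKO 1 mir-184 rose by 2.56 (adjusted p = 0.035).

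**Figure D3:**
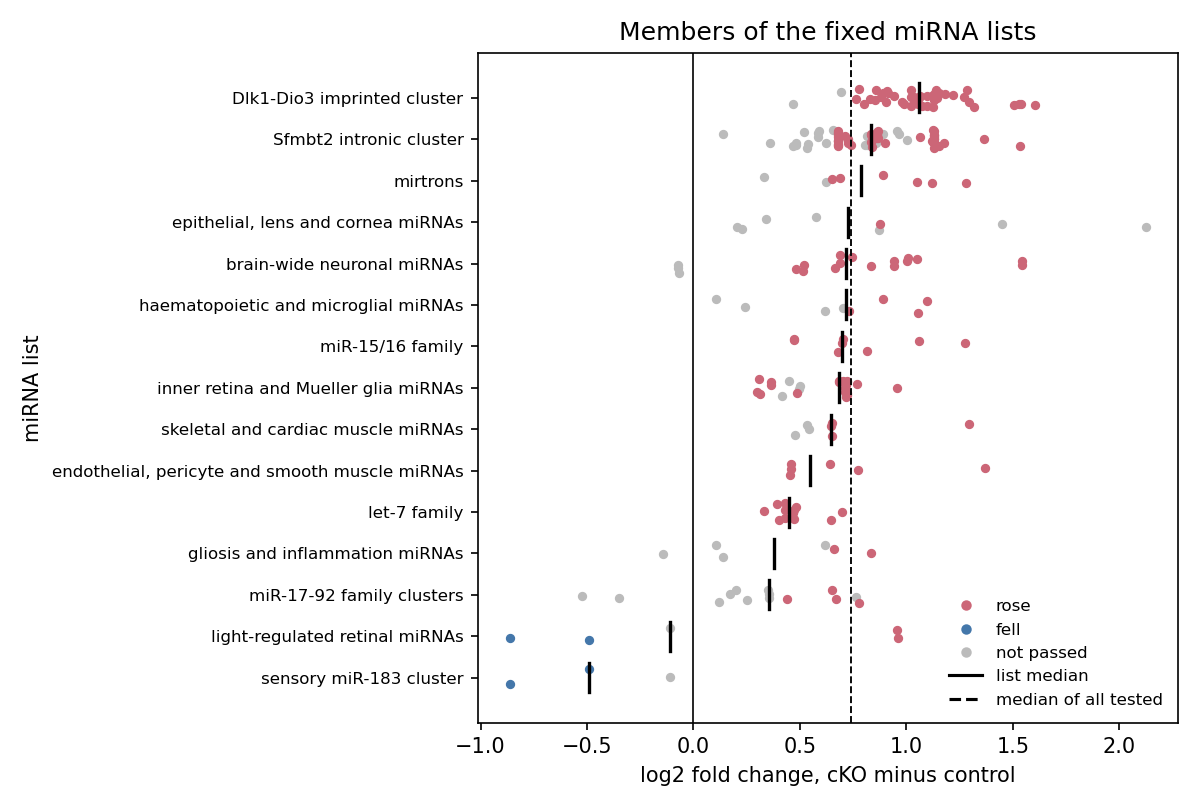
Log2 fold change, cKO minus control, of each tested member of the fixed lists, coloured by call, with list medians as bars and the median of all tested precursors as a dashed line. The Dlk1-Dio3 cluster has a median of 1.06 and the miR-183 cluster of -0.49, as deposited; with median-of-ratios scaling these are 0.33 and -1.23.

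The libraries were alike in the ranking of their miRNAs and parted by genotype in level. Spearman correlations across precursors, which are not independent replicates, ranged from 0.980 to 0.994 over the pairs of libraries. The mean was 0.990 within and 0.985 between genotypes. The first principal component held 67.9% of the variance, with control libraries between -11.4 and -5.68 and cKO libraries between 7.90 and 9.99.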

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

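Scaling changed the split of calls, and totals without mir-182 reads and both voom settings were chosen after seeing the data. As deposited 320 rose and 8 fell (328 in all). With median-of-ratios scaling 10 rose and 46 fell (56 in all), with quantile normalization 12 rose and 29 fell (41 in all), with totals free of the 10 most abundant precursors 57 rose and 29 fell (86 in all), with totals free of mir-182 reads 20 rose and 36 fell (56 in all), and with voom on whole reads plus median-of-ratios scaling 9 rose and 46 fell (55 in all). The median shift under these was 0.014, 0.042, 0.23, 0.12 and 0.0076, since each rescales the libraries. Voom on the whole reads without scaling gave 323 and 8. Summing near-identical precursors left fewer to test, and 202 rose and 7 fell (209 in all) of 296. At a mean of 100 RPKM 4 of 306 fell, and with library weights 14 fell. Leaving out single libraries gave 252 to 322 that rose and 4 to 12 that fell. The difference in the share of the 10 most abundant precursors was -1.70 points with near-identical precursors summed, because other precursors then make up the 10, and the mean correlation within genotypes was 0.984 without a filter. The planned use of other small RNAs as a reference was not run, because the values name only miRNA precursors.

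Log2 fold changes turned sign under the other scalings, which lower most precursors by construction. With median-of-ratios scaling the values were mir-181a-2 -0.023, mir-30a -0.44, mir-26a-2 -0.21, mir-30d -0.43, mir-9-2 -0.015, let-7f-2 -0.33, mir-25 -0.066, mir-143 -0.095, mir-486 -0.0039, mir-27a -0.60, mir-133a-1 -0.082 and mir-16-1 -0.26. With voom and that scaling they were mir-181a-2 -0.023, mir-30a -0.44, mir-26a-2 -0.21, mir-30d -0.43, mir-9-2 -0.014, let-7f-2 -0.33, mir-25 -0.066, mir-143 -0.094, mir-486 -0.0036, mir-27a -0.60, mir-133a-1 -0.084 and mir-16-1 -0.26. Under quantile normalization they were mir-30a -0.096, mir-30d -0.17, let-7f-2 -0.14, mir-25 -0.057, mir-145a -0.073, mir-27a -0.28 and mir-133a-1 -0.13, with totals free of the 10 most abundant mir-30a -0.21, mir-30d -0.20, let-7f-2 -0.11, mir-27a -0.37 and mir-16-1 -0.038, and with totals free of mir-182 reads mir-30a -0.32, mir-26a-2 -0.10, mir-30d -0.32, let-7f-2 -0.22, mir-27a -0.49 and mir-16-1 -0.15. The precursor mir-184 passed with a pseudocount of 10, library weights, the replicate block and voom (adjusted p = 0.011 to 0.0498). With library weights mir-378a was 0.040. Precursors near 0 turned sign when libraries were left out, with ranges of -0.43 to 0.077 for mir-183, -0.23 to 0.023 for mir-124-3, -0.085 to 0.023 for mir-378a and -0.13 to 0.035 for mir-151. Of the other values of named precursors under the alternatives, 907 kept their direction and side of the threshold, 128 lost the call and 46 gained it.

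The mean difference of these lists from the other precursors turned sign under some settings, and the cause was not tested: endothelial, pericyte and smooth muscle miRNAs (vascular), haematopoietic and microglial miRNAs (haematopoietic), skeletal and cardiac muscle miRNAs (muscle), brain-wide neuronal miRNAs (neuronal), epithelial, lens and cornea miRNAs (epithelial), miR-15/16 family, inner retina and Mueller glia miRNAs and let-7 family. Mean differences were vascular 0.053 and haematopoietic 0.023 with a pseudocount of 10, vascular 0.083, haematopoietic 0.090 and muscle 0.082 without a filter, vascular 0.021 and haematopoietic 0.10 at a mean of 100 RPKM, neuronal -0.022 and muscle 0.16 with library weights, vascular 0.10 and muscle 0.035 with near-identical precursors summed, and inner retina 0.095 and let-7 0.057 under quantile normalization. Without single libraries they ran from -0.083 to 0.11 (vascular), -0.15 to 0.073 (haematopoietic), -0.20 to 0.12 (muscle), -0.014 to 0.050 (neuronal), -0.016 to 0.39 (epithelial), -0.013 to 0.15 (miR-15/16). With the preset correlation between 3 and 5 lists were called under every setting, and with an estimated correlation 0 under every setting. With the preset correlation the Dlk1-Dio3 and miR-183 cluster lists kept direction and call under each setting, while with an estimated correlation the adjusted p ran from 0.21 to 0.63 and from 0.096 to 0.61. The light-regulated call ended under all other scalings and without a filter, and that of miR-17-92 without a filter and with near-identical precursors summed. The inner retina list was called up without a filter, with library weights, with the replicate block and without cKO 1 (adjusted p = 0.0086, 0.025, 0.032 and 0.0065). Its mean lay below the other precursors as deposited (difference -0.12) and in each fit that left out a library (-0.16 to -0.070). For this list a call up therefore does not mean a larger mean rise. The let-7 list was called down with median-of-ratios scaling, with voom and that scaling, and with totals free of mir-182 reads (adjusted p = 0.0032, 0.0035 and 0.017). Only 3 precursors make up the miR-183 cluster, which limits its test.

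Whether replicate numbers pair the libraries stays unclear. The deviations of same-numbered libraries from their group means correlated at 0.187, 0.264 and 0.00934 across precursors. Control 1 and cKO 1, and control 2 and cKO 2, correlated better with each other than with any library of another number. Control 3 and cKO 3 each correlated better with a library of another number (0.0145 and 0.0479). With the replicate block 338 rose and 10 fell.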

Other observations

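All tests of explanations in this part were chosen after the results were seen, and so were the names of mir-149, mir-378a, mir-151 and mir-423. Some abundant precursors did not pass as deposited, where the median precursor was higher: mir-378a at -0.044 (SE 0.12), mir-151 at -0.030 (SE 0.13) and mir-423 at -0.37 (SE 0.17). With median-of-ratios scaling they fell by 0.78, 0.77 and 1.11 (limma adjusted p = 0.0032, 0.0026 and 0.0023). Without control 1 mir-423 fell as deposited (adjusted p = 0.023). In the other direction mir-149 rose 2.27-fold (log2 1.19, SE 0.16; adjusted p = 3.3e-04) and stood at 0.45 after scaling (adjusted p = 0.042).

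The members of the miR-183 cluster, which are cut from a shared primary transcript, were not in a fixed ratio. There were 23.2 ± 10.7 reads at mir-182 per read at mir-183 in control and 12.9 ± 1.29 in cKO libraries (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible), with 35.5 in control 1. For mir-96 the ratios were 452 ± 129 and 342 ± 32.5 (exact two-sided permutation p = 0.3).

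The broad rise as deposited is the pattern that bears most on the rest. Reads counted at copies linked by the 1-mismatch rule do not account for it. The 233 precursors without such a copy had a median of 0.80, against 0.68 for the 228 with one. That rule missed some shared reads, since mir-148a, taken as without a copy, and mir-148b had means of 8683.33 and 8682.83 reads. Counting only the largest precursor per group still gave 103.6% of library reads in control 1 and 105.0% in cKO 2. A part of such remaining shared reads in the rise was not tested. Taking the mir-182 reads out of the totals left a median of 0.12 in place of 0.74. This follows from the shares of mir-182 whether mir-182 fell or the other precursors rose, so a fall of mir-182 in the shared total and a rise of the others cannot be told apart without an external reference. A lower share of rod RNA stays open. With 1 value per group of near-identical copies, the medians of the 6 lists for other cell types spanned 0.28. Of 10000 draws of random lists of the same sizes, 86.5% spanned as much. These lists thus moved apart no more than random ones, as they would also under a shared total. The neuronal list among them holds the pan-neuronal mir-124, so they may not be free of rod miRNAs.

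The joint rise of mir-204 and mir-211 may largely be a single measurement. Reads at mir-211 were 0.958 to 0.976 times those at mir-204 in every library. The SD of the log2 ratio was 0.00947, and 1.28% of 234 pairs of unlike abundant precursors had as small an SD (median 0.218). These pairs had a lower bound on reads but no upper bound, so mir-182 was among them. Their SD was taken over both genotypes, so pairs whose members differ in their change between genotypes have a larger SD. Reads at mir-204 beyond those at mir-211 were 0.0974% ± 0.0239 of control and 0.170% ± 0.0375 of cKO reads (SD, n = 3 each; exact two-sided permutation p = 0.1), a log2 ratio of 0.80. Whether mir-211 rose on its own cannot be told apart from this, because no reads can be assigned to it alone.

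The precursors mir-184 and mir-31 varied widely between libraries of a genotype. The values of mir-184 were 8731, 2186 and 52002 RPKM in control 1 to 3 and 23904, 57209.7 and 60098 RPKM in cKO 1 to 3. Carry-over of cornea or lens epithelium during dissection is a candidate source, but of the 7 other members of that fixed list, 0 of which are in another list, 1 (mir-31) had within-group deviations that correlated with those of mir-184 above 0.5, as did 26.3% of all other tested precursors, and the median was 0.0715 against 0.277 for those. Of those members mir-200a, mir-200b, mir-141 and mir-429 had genotype means of only 10.4 to 40.5 RPKM, where few reads make correlations unreliable. Their correlations ran from -0.622 to 0.0715, while mir-31, mir-203 and mir-205 stood at 0.918, 0.490 and 0.249. The low median therefore cannot decide on carry-over. Genotype gave an exact two-sided permutation p of 0.200 for mir-184 (n = 3 each), with overlapping groups. These explanations cannot be told apart with 3 libraries a group.

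Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. In limma the real split called 328 precursors as deposited and 56 with median-of-ratios scaling, and the highest other split called 0 in either case, so 1 split of 10 reached the real count. Every other split mixes the genotypes in both groups, so a genotype difference adds to the spread within groups and lowers the calls. The counts of 0 therefore do not gauge false calls. For the lists, with the preset correlation, the real split called 4 and the highest other 7. At least as many were called by 5 of the 10 splits, the real one included. The number of lists called with the preset correlation thus does not set the real split apart.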
